A study of Caenorhabditis elegans with 2 samples.

How the data were processed

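The data are ChIP-seq peak lists for LSY-2 carrying a GFP-FLAG tag, from 2 biological replicates of whole L4 larvae of 1 strain. The authors deposited, for each of the ce10 and ce11 builds, a list of 30000 peaks and background regions per replicate, a list of 30000 from both replicates pooled, and a list thresholded by IDR. Per the deposited notes, the lists were made from the alignments and a control alignment. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control experiment itself was not analysed here. The signal of each peak is the deposited value, whose scale is not given in the sources used here, so it was used for ranks and for comparison within a list and, between the replicates, on the log2 scale. The deposited lists also give a -log10 q-value, capped at 4.30 in replicate 1 and 4.28 in replicate 2 and reached by 10031 and 9633 peaks, and it was used only to describe the lists. The summit position is counted from the start of the peak. The depth per library is not given by peak lists and is unknown, so that intervals cover counting error over peaks or genes only.

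The main list was the thresholded ce11 list of 5944 peaks, which cover 1785.62 kb with a median width of 360 bp and hold 48 peaks that share an interval with another. It was the same as the 5944 strongest peaks of the pooled list. The ce10 list had 5803 peaks, and no coordinates were converted. Genes came from the Ensembl release 115 annotation of WBcel235, which is the ce11 sequence, and no peak of the ce11 lists ended beyond a chromosome end. MicroRNA symbols were taken from the RefSeq annotation through WormBase identifiers. The mitochondrial genome was left out.

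Replicates were compared by the overlap, of at least 1 bp, of their 5944 strongest peaks and by correlation of log2 signal at summits matched within 200 bp, with 1000 bootstrap draws over peaks for the interval of rho. Chance placement was measured by 1000 circular shifts along each chromosome, whose smallest p is 0.000999 one-sided and 0.002 two-sided. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of any protein-coding or microRNA transcript. A gene with several 5′ ends had a window for each, and the number of windows per gene was not adjusted for. The annotation classes were taken in the order promoter, 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. For 35 gene lists, the share of members with a summit in the window was compared with all other protein-coding genes. The microRNA list was compared with all other microRNA and protein-coding genes. In other lists, microRNA members were counted as members. The tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists, called at an adjusted p under 0.05. For counts of 0, 3 counts of the total give the limit stated, and 0.5 was added to each cell for the odds ratio. Names that matched no gene were lsy-15, ift-140, rad-54, elt-5, lep-5, swsn-8 and cdc-45. Non-coding genes were counted with a summit within 200 bp and compared with the shifts, adjusted over 5 classes. Words of 6 bases, both strands collapsed, were counted in the 100 bp at each summit and in a flank of 100 bp starting 200 bp away. Odd-ranked peaks chose the 10 words of smallest p and even-ranked peaks tested them. Chromosome centres and arms each took equal total lengths, with the arms at both ends. Interactions were tested in logistic models.

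The gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. The rule named the genes at the 20 strongest peaks, every member of the ASE asymmetry list, and, for each other list called, the 3 members with the strongest summit. Alternatives were the 2972 strongest peaks, each replicate alone, the pooled list, windows of 500 bp and 2000 bp, the whole peak interval, named genes as background, the length of the upstream gap as a covariate in a logistic model, and the nearest gene only. For the replicates, they were overlap of 50% of both peaks, summits within 100 bp, all peaks and the ce10 lists. For words, flanks at 400 bp and words of 8 bases were tried. Counting 1 summit per interval, and leaving out the lists called lower from the chromosome tests, were added after seeing the data.

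The methods were tested on simulated data. Lists planted at an odds ratio of 5 were called in 100% of 200 tests and lists planted at 0.2 in 72%, and 99.0% of 1157 unplanted lists were not called. Genes were drawn independently there, whereas neighbouring genes can share a summit in the data. The simulations do not cover that dependence, and the p-values of the lists describe how the peak list falls on genes. The promoter test left 95.5% of 200 simulations without enrichment uncalled. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.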

Results

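LSY-2, a zinc finger transcription factor known for its role in the left-right asymmetry of the ASE taste neurons, was profiled by ChIP-seq in whole Caenorhabditis elegans worms at the L4 larval stage. The worms, of mixed sex, carried an integrated transgene that expresses LSY-2 with a C-terminal GFP-FLAG tag, and chromatin was fragmented by sonication. The series held 1 group of 2 biological replicates. Each replicate had its own list of 30000 peaks and background regions, and the list thresholded by the irreproducible discovery rate (IDR) held 5944 peaks on the ce11 build. The lists gave no read counts, so the depth of each library is unknown. Signal values of the thresholded peaks ran from 59.9 to 19064.5 with a median of 114.8, and the 20 strongest peaks held 11.5% of the summed signal. A summit in a promoter window locates enrichment and does not measure occupancy in any cell type, since whole animals were used.

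The first comparison asked whether both replicates found the same sites. The strongest sites were the same in both: all 20 of the strongest thresholded peaks ranked among the 20 strongest of each replicate. The peak upstream of rpl-3, which encodes a protein of the large ribosomal subunit, ranked 1 in both replicates, with a signal of 10359 in replicate 1 and 8787 in replicate 2. The peak upstream of rpl-20 ranked 2 in both, and that upstream of cox-5A, a subunit of cytochrome c oxidase, ranked 3 in both. Of the 5944 strongest peaks of replicate 1, 4570 (76.9%) overlapped one of the 5944 strongest of replicate 2. Circular shifts of the replicate 2 peaks along each chromosome gave a median of 3.77% and at most 5.1% in 1000 shifts, with a one-sided permutation p of 0.000999, the smallest the shifts can give. The reverse comparison also gave 76.9%.

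Peak heights followed each other across the 5823 thresholded peaks (98.0%) matched to a summit within 200 bp in both replicates. Spearman's rho was 0.790, with a bootstrap 95% interval of 0.778 to 0.803, and Pearson's r of log2 signal was 0.872. These are correlations across peaks, and peaks are not independent replicates. The median log2 difference, replicate 1 minus replicate 2, was 0.51 ± 0.61 (SD over peaks), a ratio of 1.42. The agreement fell with rank. In replicate 1, 99.4% of peaks ranked 1 to 1000 overlapped any peak of replicate 2, and 48.6% of those ranked 29001 to 30000, against a mean of 18.9% over a part of the shifts for each of these bins. Of the thresholded peaks, 4349 (73.2%) were among the 5944 strongest of both replicates, and 146 (2.46%) were among those of neither. By a cut at rank 15000, a few rested on 1 replicate. Of these, 120 (2.02%) were among the 5944 strongest of replicate 1 and ranked beyond 15000 or unmatched in replicate 2. Another 65 (1.09%) showed the opposite. The peak at the cytochrome P450 gene cyp-13A2 was one of the 120, ranked 2418 in replicate 1 and 28504 in replicate 2.

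**Figure D1:**
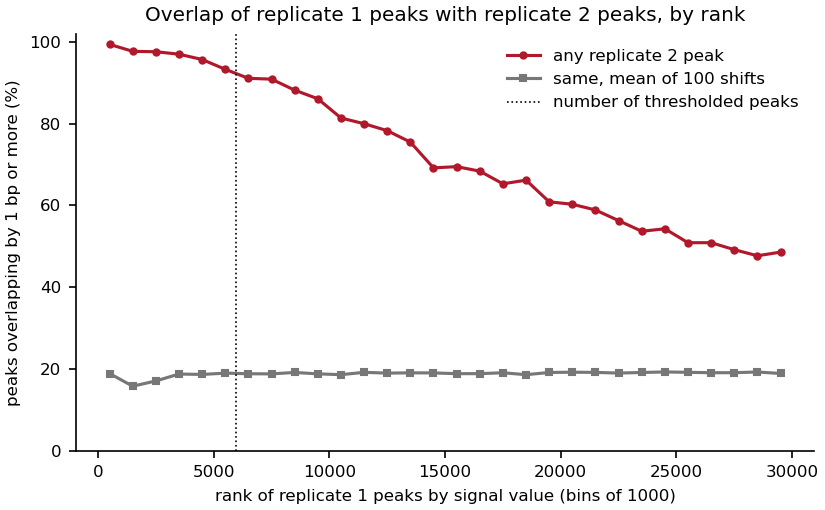
Percent of replicate 1 peaks that overlap any replicate 2 peak, in successive bins of 1000 peaks ranked by signal, with the mean over a part of the 1000 circular shifts for comparison. The overlap falls from 99.4% in the bin of strongest peaks to 48.6% in the bin of weakest peaks, above the shifts in every bin.

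The next comparison asked where LSY-2 peaks lie relative to genes. Peaks concentrated upstream of genes and were depleted from coding sequence. The peak of highest signal lay at III:3867004-3867861, with its summit 283 bp upstream of rpl-3 (signal 19064.5). Next came the region between rpl-20 and Y17G9B.5 (15870), that upstream of cox-5A (12289), and that between rpl-15 and K11H12.8 (11998). Of the 20 strongest peaks, all 20 had their summit in a promoter window, and 14 lay between the 5′ ends of genes on opposite strands, so that 37 genes are named by 20 peaks.

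The others among these 20 peaks fell by signal as follows. The summit between rps-20 and ekl-4, which also lies upstream of the microRNA mir-354, had a signal of 9453. The summit between ifet-1, a translational regulator, and rps-1 had 8987. Those at cct-8, a subunit of the cytosolic chaperonin, with Y55F3AR.2, and at the syntaxin gene syx-5 with F55A11.1 had 8787 and 8395. The summit at lin-53, which encodes a histone-binding protein, with nra-2 had 8372, and that at gmps-1 with cap-2, an actin capping protein, had 7829. The summit at the Dishevelled gene mig-5 with the chaperonin gene cct-1 had 6304, that at Y25C1A.8 had 6225, and that at lin-7 with Y54G11A.17 and elof-1 had 5573. The summit at lin-9, a member of the DREAM complex, had 5502, and that at clsp-1 with the elongation factor gene eef-2 had 5303. The summit at mcrs-1 with the ATP synthase gene atp-1 had 5243, that at cup-14 with ndub-8 had 5205, and that at serp-1.1 had 5087. The last of the 20 were at eef-1A.1 with mir-5549 and rfc-4 (5017) and at rpl-11.2 (4909).

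Of the 5944 summits, 3393 (57.1%) lay from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding or microRNA transcript. The shifts gave a median of 26.2% and a range of 24.1% to 28.4% (2.18-fold, two-sided permutation p = 0.002, the smallest the shifts can give). Among the 1000 strongest peaks, 80.8% lay in this window, with a median position 176 bp upstream of the nearest 5′ end, and among the 1000 weakest 41.8% did. In exclusive classes, 54.8% of summits were in promoters against 22.4% in the shifts (2.45-fold), and 3.95% in other exons against 2.66% (1.49-fold). Other exons include those of tRNA genes, and 74 summits lay inside a tRNA gene, so this fold can overlap with the tRNA result below. Coding exons held 1.90% against 20.9% (0.0909-fold), introns 14.8% against 29.4% (0.503-fold) and 3′ UTRs 1.40% against 2.62% (0.532-fold). Each of these 5 classes had an adjusted p of 0.0028, from the smallest p the shifts can give. Among the 2972 strongest peaks, the fold was 2.95 for promoters, 1.25 for other exons, 0.0337 for coding exons, 0.334 for introns and 0.231 for 3′ UTRs. The share in 5′ UTRs, 1.35% against 1.08%, did not pass the test (adjusted permutation p = 0.0723), but it did with either replicate alone. Intergenic sequence held 21.8% against 20.9% (permutation p = 0.154), and its fold turned to 0.860 among the 2972 strongest peaks (permutation p = 0.002).

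**Figure D2:**
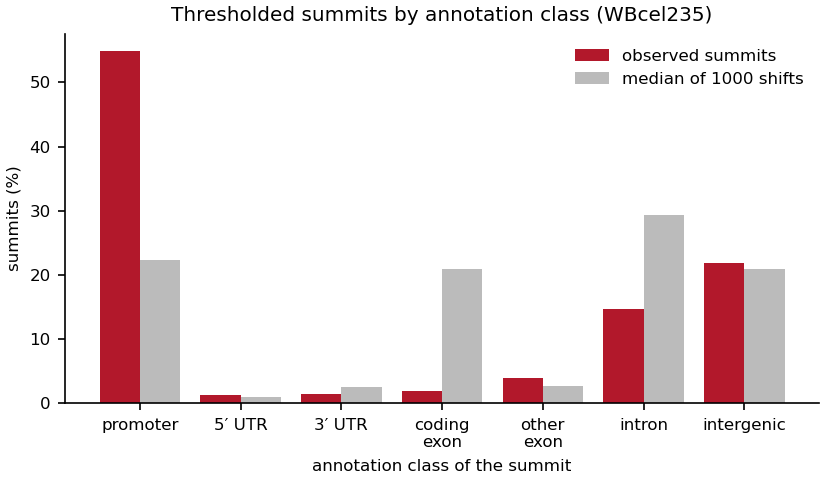
Percent of the 5944 thresholded summits in each exclusive annotation class, beside the median of 1000 circular shifts. Promoters hold 54.8% of summits against 22.4% in the shifts, and coding exons 1.90% against 20.9%.

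Gene lists were then compared, to ask which groups of genes carry LSY-2 at their promoters. Genes of protein synthesis, protein turnover and respiration carried summits most often when a summit counted for every gene whose window held it. Of the 77 cytosolic ribosomal protein genes, 68 (88.3%) had a promoter summit, against 19.2% of other protein-coding genes (odds ratio 31.7, 95% interval 15.8 to 63.6, adjusted exact p = 1.46e-37), and the median signal at their summits was 987. Translation initiation and elongation factors followed with 35 of 42 (odds ratio 20.8), proteasome subunits with 27 of 33 (18.7), such as pas-4 (signal 4134), rpn-5 (3602) and pas-6 (1481), and respiratory chain and ATP synthase genes with 39 of 51 (13.5), among them cox-14 (4189). With each summit given only to the gene of the nearest 5′ end, the odds ratios of these 4 lists were 5.84, 8.34, 9.92 and 8.12, and all were still called, but the order changed: the heterochronic pathway had 9.42, chromatin modifiers 7.46 and pan-neuronal genes 6.46. In all, 3897 of 19973 protein-coding genes (19.5%) had a promoter summit, and 12 of the 35 lists were called higher and 7 lower by two-sided Fisher's exact tests at an adjusted p under 0.05.

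Regulators of chromatin, of the cell cycle and of developmental timing were among the lists called higher. The heterochronic pathway, which times larval development, had a summit at 17 of its 24 genes (70.8%, odds ratio 10.05, 95% interval 4.16 to 24.2, adjusted exact p = 1.91e-07). Its strongest summits were at nhl-2, a cofactor of microRNAs (935), the Pumilio gene puf-9 (863) and lin-46 (482). Among its best known members, singled out after their values were seen, lin-28 had a signal of 414, lin-14 118, lin-4 70.2 and let-7 61.9. The values of lin-4 and let-7 lie near the lowest signal of the thresholded list, 59.9. Chromatin modifiers had a summit at 30 of 44 genes (odds ratio 8.90), with the acetyltransferase gene cbp-1 (4351), set-26 (2778) and the methyltransferase gene set-16 (980) on top. The synMuv B and DREAM repressors had 14 of 25 (5.27), led by lin-53, lin-9 and lin-54 (1426). Cell cycle and DNA replication genes had 28 of 45 (6.84), such as mat-1 (1057), mcm-4 (755) and pcn-1 (724). Splicing and mRNA processing genes had 34 of 50 (8.83), such as prp-8 (3267), rsp-6 (2808) and rsp-5 (2447). Chaperones had 35 of 61 (5.59), with dnj-14 at 1918 after cct-8 and cct-1, and given to the nearest gene only their odds ratio was 2.56. The vacuolar ATPase had 11 of 20 (5.05), with vha-1 (687), vha-8 (532) and vha-15 (485). The odds ratio of the heterochronic pathway was 5.71 without replicate 1, 4.43 with a window of 500 bp and 15.9 with 2000 bp. Chromatin modifiers had 4.80 with 500 bp and the vacuolar ATPase 9.56 with 2000 bp, and splicing genes 5.67 with the nearest gene only.

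Neuronal genes divided by kind. Pan-neuronal synaptic and vesicle genes were called higher, with a summit at 16 of 30 (53.3%, odds ratio 4.73, adjusted exact p = 8.76e-05). Their odds ratio was 2.72 without replicate 1, 2.79 for the 2972 strongest peaks, 4.01 with a window of 500 bp and 8.77 with 2000 bp. The median signal of their summits was 137, against 169.9 over all genes with one, and the strongest were at the synaptobrevin gene snb-1 (238), ric-19 (182) and rab-3 (179). The rab-3 summit lay inside the annotated gene, upstream of an internal 5′ end. Genes with more 5′ ends offered more windows, which no alternative adjusted for in any list. Chemoreceptor genes were nearly free of summits, with 9 of 1264 (0.712%, odds ratio 0.0273, adjusted exact p = 1.86e-105), among them srh-16 (504), sri-5 (394) and sri-39 (201). Neuropeptide genes had 5 of 147 (3.4%, odds ratio 0.144, or 0.264 without replicate 1), among them nlp-4 (1612), ins-39 (644) and flp-23 (114). The ASE asymmetry list, which holds the pathway LSY-2 is known for, had a summit at 4 of its 24 genes (16.7%) against 19.5% of the others, with an odds ratio of 0.825, a 95% interval of 0.282 to 2.41 and an adjusted p of 1. The 4 were lin-49 (250), the Groucho corepressor gene unc-37 (178), lsy-13 (176) and lsy-12 (85.3), which are widely acting chromatin and repressor genes. The stronger of 2 lsy-12 summits, given here, lay inside the annotated gene, upstream of an internal 5′ end. No thresholded summit lay in the promoter window of lsy-6, cog-1, die-1, che-1, ceh-36, lim-6, fozi-1, nsy-7, tbx-37, tbx-38, ztf-6, lsy-2, gcy-4, gcy-5, gcy-6, gcy-7, gcy-14, gcy-22, flp-4 or flp-20. The ASE neurons are few among the cells of a larva, and enrichment confined to them was not measured separately here.

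The other 5 lists called lower were gene families. C-type lectins had a summit at 3 of 238 genes (1.26%, odds ratio 0.0519, or 0.0863 without replicate 2), namely clec-126 (289), clec-53 (221) and clec-87 (152). F-box families had 18 of 321 (5.61%), led by fbxc-23 (1834), fbxb-85 (706) and fbxb-58 (639). Cuticle collagens had 10 of 174 (5.75%), led by col-38 (1782), col-71 (280) and col-8 (261). Cytochrome P450 genes had 4 of 74 (5.41%), among them cyp-13A2 (112.3), whose rank differed between the replicates as given above, cyp-43A1 (94.7) and cyp-31A3 (78.7). Major sperm protein genes had 0 of 31, which allows a share of up to 9.68% (adjusted exact p = 0.00409), a call that ended among the 2972 strongest peaks (adjusted p = 0.0503).

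The other 15 lists did not pass the test. P granule and small RNA germline genes had a summit at 13 of 40 genes (32.5%, adjusted exact p = 0.0797), and passed without replicate 1 (adjusted p = 0.0157). Vulval induction and Notch/Ras genes had 12 of 40 (30%, adjusted exact p = 0.180), and passed with a window of 2000 bp (adjusted p = 0.0156). Homeobox genes had 13 of 94 and nuclear hormone receptors 47 of 269, and each passed as lower under 2 alternatives. The counts were 6 of 25 for ztf genes, 8 of 34 for hypodermis regulators, 9 of 40 for meiosis genes, 50 of 257 for microRNAs and 8 of 42 for cilium genes. They were 11 of 58 for histone genes, 7 of 38 for intestinal genes, 7 of 41 for muscle genes, 6 of 49 for spermatogenesis genes and 3 of 25 for bHLH factors. Vitellogenins had 0 of 6, which allows a share of up to 50%.

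**Figure D3:**
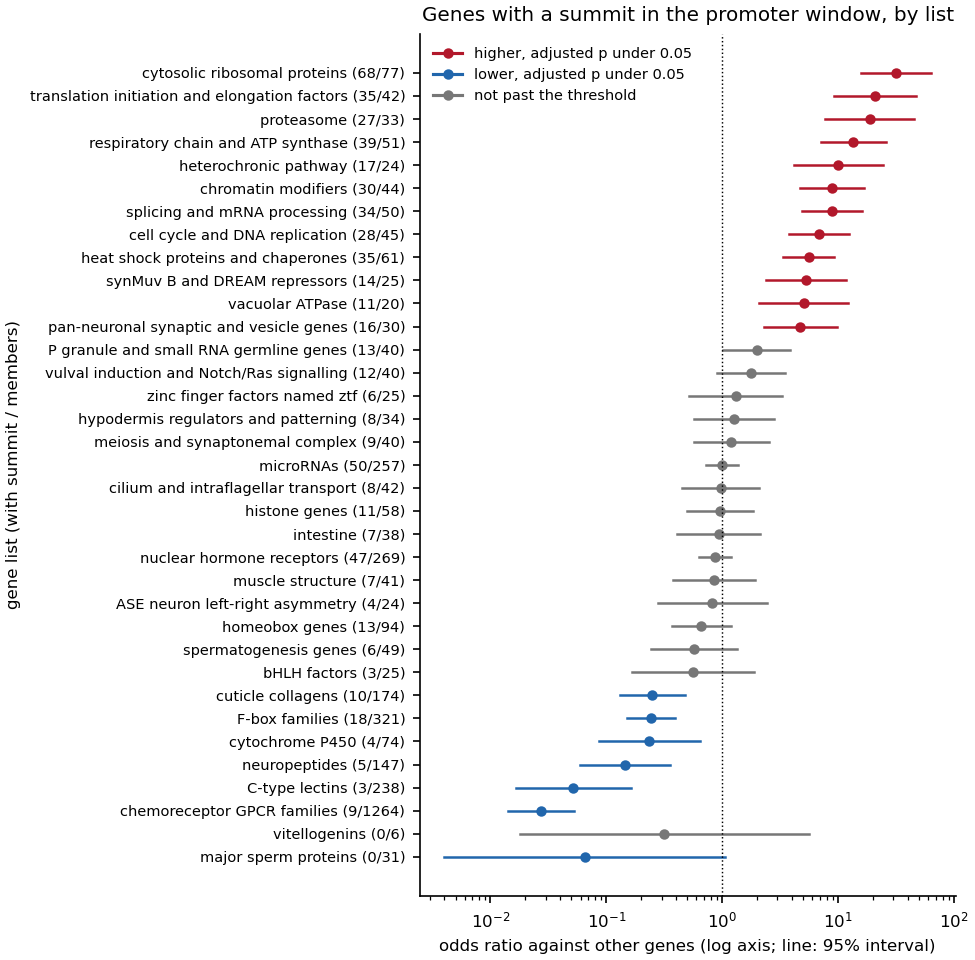
Odds ratio of a promoter summit for the members of each of the 35 gene lists against other genes, on a log axis with 95% intervals, coloured by the call. Counts stand beside the names, and 0.5 was added to each count where a list had no summit. The 12 lists called higher run from pan-neuronal genes (4.73) to cytosolic ribosomal proteins (31.7).

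Genes for small non-coding RNAs were compared next. Transfer RNA genes carried peaks far more often than chance placement gave: 187 of 612 (30.6%) had a summit within 200 bp, against a mean of 2.62% in the shifts (11.7-fold). Small nucleolar RNA genes had 87 of 346 (25.14%, 7.60-fold) and small nuclear RNA genes 24 of 129 (18.6%, 6.41-fold). MicroRNA genes had 17 of 261 (6.51%, 2.23-fold, adjusted permutation p = 0.00999). The shifts spread summits over whole chromosomes, so these folds do not compare the classes with other genes. In promoter windows, the microRNA list was not called against other genes (19.46% against 19.51%, odds ratio 0.996). The adjusted p of the tRNA, snoRNA and snRNA classes was 0.00333 each, from the smallest p the shifts can give. No rRNA gene of 20 had a summit, which allows a share of up to 15%, and the test could not tell this from chance (permutation p = 0.911). Counting summits within 500 bp lowered the fold of tRNA genes to 5.96, of snoRNA genes to 4.97 and of snRNA genes to 3.22 and raised that of microRNA genes to 3.04, with all 4 still called. With the 2972 strongest peaks, the folds were 12.5 for tRNA, 12.1 for snoRNA, 10.3 for snRNA and 2.95 for microRNA genes.

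The sequence at the summits was compared with flanks of the same peaks. Words built of GAGAGA and AGACGCAG marked the summits, and AT-rich words were scarce there. In the 2972 even-ranked peaks kept for testing, GAGAGA lay in 25.7% of summit windows of 100 bp and 7.54% of flanks, and AGAGAG in 22.6% and 5.69%. The words AGAGAC (17.8% and 3.94%), CGTCTC (15.2% and 3.03%), GACGCA (14.2% and 2.05%), ACGCAG (13.9% and 1.99%) and AGACGC (12.8% and 2.56%) were also more frequent at summits. AAAATT (19.2% and 43.8%), AAAAAT (26.9% and 49.5%) and TTAAAA (10.5% and 28.5%) were less frequent. Adjusted p-values of these 10 words, from exact two-sided McNemar tests, lay between 2.04e-94 and 1.76e-54. Among words of 8 bases, AGACGCAG was in 9.02% of summit windows and 0.639% of flanks, and GCAAACAC in 5.15% and 0.740%. Summits were richer in GC than flanks, 43.6% against 35.2%, a mean difference of 8.46 ± 11.2 percentage points (SD over 5944 peaks).

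The word AGACGCAG lay within 50 bp of 553 summits (9.30%). It occurs at 5812 places in the genome, of which 595 (10.2%) were within 50 bp of a summit, and 16.6% of its occurrences in promoter windows were. Its relation to signal, examined after the words were found, differed by location. Outside promoter windows it was in 14.9% of the strongest 638 summits and 5.65% of the weakest 637 (ratio 2.63, two-sided Fisher's exact p = 5.59e-08). In promoter windows it was in 9.66% of the strongest 849 and 8.37% of the weakest 848 (ratio 1.15, exact p = 0.397), and the interaction of signal and location in a logistic model had p = 4.86e-08. GAGAGA rose with signal outside promoter windows, from 23.5% to 38.4% (Fisher's exact p = 1.12e-08). In promoter windows it did not change steadily: from the strongest to the weakest group it was 15.9%, 29.1%, 24.8% and 22.9%. The strongest group was lower than the weakest (Fisher's exact p = 0.000288), and the interaction of signal and location in a logistic model had p = 1.48e-11. That model assumes a steady trend with signal, which GAGAGA lacked in promoter windows.

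**Figure D4:**
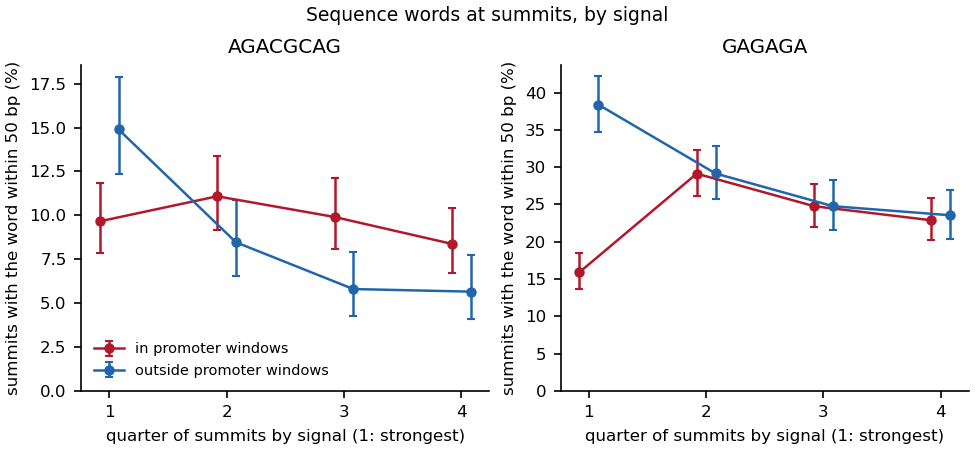
Percent of summits with AGACGCAG or GAGAGA within 50 bp, in 4 groups of equal size ordered by signal, for summits in and outside promoter windows, with Wilson 95% intervals. Outside promoter windows AGACGCAG falls from 14.9% in the strongest group to 5.65% in the weakest, and in promoter windows it is 9.66% and 8.37%.

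Chromosomes differed in how many of their genes carried a summit. Chromosome III had the highest share, 31.7% of its protein-coding genes, followed by I with 28.6%, II with 19.7%, IV with 18.5%, X with 14.1% and V with 11.3%. Genes on X had a summit less often than autosomal genes, 385 of 2731 against 3512 of 17242 (20.4%), with an odds ratio of 0.642 (95% interval 0.572 to 0.719, two-sided Fisher's exact p = 2.39e-15). On the autosomes, genes in chromosome centres had one more often than genes on arms, 23.5% against 16.4% (odds ratio 1.57, 95% interval 1.45 to 1.69, exact p = 5.47e-31). On X the shares of centre and arms were 14.1% each (odds ratio 1.00, 95% interval 0.807 to 1.24, exact p = 1), and a logistic test of the difference between X and autosomes, run after this was seen, gave p = 0.000134. Neighbouring genes share peaks and are not independent, so these p-values describe how the peak list falls on genes.

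The locus of the tagged gene was examined because the transgene carries lsy-2 in its genomic surroundings. No thresholded peak lay within 20 kb of lsy-2 (X:2089704-2093256, plus strand), and none within 50 kb. The nearest summits were 74.9 kb to one side and 51.2 kb to the other. Each replicate had 1 peak of its own within 20 kb, of signal 8.41 in replicate 1 and 5.59 in replicate 2, against a median of 9 peaks in the 404 other windows of this size on X. Of 171 windows of X with 50 kb on either side, 14 (8.19%) had no thresholded peak.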

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

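Counting 1 summit per interval and leaving out the lists called lower were chosen after seeing the data. Under every alternative tried, the replicate overlap, the promoter share, the depletion from coding exons, introns and 3′ UTRs, the 12 lists called higher, the chromosome differences and the tRNA, snoRNA, snRNA and microRNA enrichments over the shifts kept their direction and their side of the threshold. Odds ratios of the 12 lists ranged from 2.56 to 50.3. Of the 10 words chosen anew under each alternative, 7 to 9 were more frequent at summits, and whether the reported words kept their tests was not examined. The pooled list is the same by construction. The Spearman correlation of peak signal between the replicates was 0.812 with summits within 100 bp and 0.836 for the 2972 strongest peaks. The intergenic fold was 0.860 for the 2972 strongest peaks and 0.995 to 1.04 with each replicate alone, and the 5′ UTR fold was 1.30 to 1.38 with each replicate alone, past the threshold in both. Odds ratios of lists not called in the report crossed 1 as follows. For the 2972 strongest peaks they were 0.865 for hypodermis regulators, 0.885 for ztf genes and 1.04 for histone genes. With each replicate alone they were 1.18 to 1.30 for histone genes, 0.763 to 1.09 for intestinal genes and 0.959 to 1.01 for microRNAs. With 500 bp they were 1.05 for ASE genes, 1.08 for muscle genes, 0.326 for hypodermis regulators and 1.09 for histone genes, and with 2000 bp 1.13 for cilium genes and 1.24 for microRNAs. With the whole interval, microRNAs had 1.17. With named genes as background they were 0.912 for meiosis genes, 0.967 for hypodermis regulators and 0.992 for ztf genes. With the nearest gene only they were 1.16 for muscle genes, 1.27 for intestinal genes and 1.13 for nuclear hormone receptors. The cause was not tested. Beyond these, 356 values for single lists kept their direction and their side of the threshold, though not their size, 6 passed the threshold in addition and 1 no longer did. The model with the upstream gap could not be fitted for major sperm proteins and vitellogenins. No paired analysis was possible because the series holds 1 group. The unknown depth leaves open whether sites missing from the lists are bound weakly.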

Other observations

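Of the tests in this part, those of GCAAACAC, of words in strong against weak promoter peaks and of X without the low lists were chosen only after the result was seen, as was the use of the planned nearest-gene alternative to test divergent promoters. Strong and weak promoter peaks carried different words. Among even-ranked members of the strongest and weakest of 4 groups of promoter summits, 424 each, ACCGTA was in 24.1% of strong and 7.31% of weak summits, GCGCCA in 14.9% and 2.59%, and AACGCG in 18.6% and 4.72%. TGATAA, which contains the core bound by GATA factors, went the other way, with 2.59% and 15.8% (adjusted exact p = 7.31e-11). GC content fell from 47.6% in the strongest group to 40.6% in the weakest, which favours GC-rich words at strong summits. Among words of equal GC content, ordered by the ratio of strong to weak summits, ACCGTA ranked 10 of 546, GCGCCA 3 of 152 and AACGCG 11 of 379, and TGATAA ranked 2 of 182 in the opposite order. Of the other words of the 10, CCGTAC ranked 2 of 379, AGTACG 12 of 546, GCGTAC 15 of 379 and ACGCGC 16 of 152. GAGCGC (59 of 152) and ACGGTA (83 of 546, in 11.6% and 6.60%) were ordinary for their GC content. Of the 168 summits near tRNA genes, 74 (44.0%) fell inside the tRNA gene, and 71 (42.3%) lay on X, where 276 of the 612 tRNA genes lie. Their median signal was 118 against 114.7 for other summits.

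The strong peaks at promoters of translation, proteasome and respiratory genes may reflect recovery of accessible promoters irrespective of their sequence. The test of this was set after the word AGACGCAG was found but before its own result was seen. It came out as that explanation predicts. The word was only 1.15 times as frequent in the strongest as in the weakest promoter summits (exact p = 0.397). That word was taken from these same peaks and was not shown to be the site LSY-2 binds. A flat share therefore does not decide between accessible promoters and LSY-2 binding. A word chosen later from the 10 words of 8 bases, GCAAACAC, was 5.1 times as frequent in the strongest (12.3% against 2.41%), but it ranked 17 among 68 words of its GC content in a like comparison. Another, GCGCCAGC, was in 7.31% against 0.236%, ranked 1 of only 3 words of its GC content, but accessible promoters with words for other factors would give the same, so neither word settles the matter. Divergent promoters counted for both genes cannot account for all of the size. The odds ratio of ribosomal protein genes fell from 31.7 to 5.84 with the nearest gene only and was still called. That rule also gives some summits to the neighbour alone, such as that between rpl-20 and Y17G9B.5 to Y17G9B.5. How much of the fall is due to double counting was not separated. Within 10 classes of promoter GC content, the odds ratio of ribosomal protein genes was 27.1. No accessibility data, other factor or control experiment was used here, so accessible promoters remain open, and with 1 group no biological explanation was tested.

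For the peaks at tRNA genes, reads shared between identical copies were examined through the 143 tRNA genes of unique sequence. Of these, 21.7% had a summit, against at most 6.29% in the shifts. A unique gene can be counted for the summit of a neighbouring tRNA gene that has copies. This comparison therefore cannot decide whether such reads are the whole cause. Genes with identical copies had a summit more often, 33.3% of 469 (odds ratio of unique genes against copies 0.555, exact p = 0.00937). How reads that match several copies were placed is not given, so this difference does not show whether shared reads contribute. The word AGACGCAG was 0.125 times as frequent at tRNA summits as at others (2 of 168 against 551 of 5776, exact p = 1.91e-05). Its absence argues against that word as the source of most of these peaks, though most other summits lacked it too. Identical tRNA copies repeat the same sequence, so the exact test counts summits as independent that are not. Reads shared with a similar or neighbouring tRNA gene cannot be told apart from separate peaks: 1 of 16 genes without such a neighbour (6.25%) had a summit, and the shifts gave up to 25%. No biological explanation was tested.

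Extra copies of the lsy-2 region, carried by the transgene, could raise background and give peaks at the locus. The data argue against it at this depth, since at most 10.6% of equal windows of X had fewer peaks of a replicate's own than the lsy-2 window. Copies corrected for by the control remain open. No biological explanation was tested.

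A hypothesis on X was that families without summits, such as chemoreceptors, are spread unevenly over chromosomes and could lower its share. The gene counts argue against it: X holds 2731 of the 19973 protein-coding genes but only 127 of the 2249 in the 7 lists called lower. Leaving those out, which were chosen for lacking summits, therefore had to move the odds ratio of X against autosomes away from 1, and it was 0.576. Chromosome V, which lost 1120 genes this way, then had a share of 14.3% against 14.6% for X. The difference between centres and arms of autosomes remained at an odds ratio of 1.41 (exact p = 3.45e-18).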
